A study of Mus musculus with 25 samples.

How the data were processed

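Bulk RNA sequencing had been carried out on mouse retina in 25 libraries, 5 in each of 5 groups. Per the labels, the groups were retinas of wild-type mice given AA147, Ceapin-A7, tunicamycin or vehicle by intravitreal injection, with the vehicle libraries in 2 sets of 5. The treatment label of both vehicle sets reads PBS, whereas the protocol describes saline with 0.05 to 0.1% dimethyl sulfoxide. Nothing in the labels states that the libraries of a group came from separate animals, and both eyes were injected. The p-values therefore measure the spread between libraries, which may be technical.

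Per the labels' protocols, the cornea and lens were removed, RNA was extracted from the retina and stranded mRNA libraries were made for DNBSEQ sequencing. The expression values deposited by the authors were in FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, with 2 decimals, in 1 table per group. The submitters' processing notes name HISAT2 2.0.4, RSEM 1.2.18 and DESeq2 1.4.5 and the mouse build GRCm39, without giving the order or the role of each. Columns were matched to samples by their names, and 0 columns of per-library values were left out. The annotation used here for gene lengths and GC content belonged to an earlier mouse build, so no coordinates are given.

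The 5 tables listed 2 different sets of genes. The tables of vehicle set 1 and AA147 listed the same 18676 genes, and those of vehicle set 2, tunicamycin and Ceapin-A7 the same 19102 genes. These are called table families below. The 18440 genes found in both were used, and 236 and 662 genes listed in 1 family only were left out of the tests. Levels set across families thus compare tables that list different genes, and the counts, lists, scores and most named genes are also given against the vehicle set of the same family.

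FPKM holds no counts, so no count model was used. Depth was estimated roughly from the steps between low FPKM values of 2718 single-transcript genes, assuming that 250 bases of each transcript cannot start a fragment. The estimate was 15.2 to 24.9 M fragments per library, with a median of 23.4 M. At the estimate the low values lay 0.122 to 0.172 from a whole number of fragments on average, so whole fragments were not recovered gene by gene. A single depth gives 0.25 by chance, but the estimate is the best of many depths. The best depth away from the estimate gave 0.172 to 0.231. On 6 simulated depths the largest error was 0.667%, with the same 250 bases assumed, so that assumption was not tested. At the median depth, 1 FPKM over a 2 kb transcript corresponded to 46.8 fragments.

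Values were tested as log2(FPKM + 1), a scale that understates the change of low genes. Genes with at least 1 FPKM in at least 5 of the 25 libraries were kept, 13117 in all. One linear model with all 5 groups was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior. Each SE and p-value of limma thus rests on a spread pooled over the 5 groups, which understates that of a more variable group. All tests were two-sided. A gene was called for a compound when its Benjamini-Hochberg adjusted p was under 0.05, taking the larger of the p-values against the 2 vehicle sets, and its direction was the same against both. The change given is against the mean of both vehicle sets unless stated otherwise. AA147 was also compared with Ceapin-A7, and vehicle set 2 with vehicle set 1, by the same model. Tunicamycin against Ceapin-A7, and tunicamycin against AA147 with each relative to the vehicle set of its own family, were added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the depth estimate and the figures.

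Gene lists, 33 in all, were fixed before the data were examined, and 30 had at least 3 tested genes. They were ATF6 targets and ER chaperones, IRE1-XBP1 targets and ER translocation, PERK-ATF4 targets, N-glycosylation, NRF2 oxidative stress, cytosolic heat shock, apoptosis and p53, sterol synthesis, markers of rods, cones, bipolar, amacrine, horizontal and ganglion cells, axon injury, Muller glia, reactive gliosis, microglia, neutrophils, cytokines, interferon and antigen presentation, endothelium, pericytes and smooth muscle, pigment epithelium, lens, cornea, fibroblasts and matrix, erythrocytes, the circadian clock, immediate early genes, mitochondrially encoded genes, cytosolic ribosomal proteins and sex-linked genes. Each list was tested with camera in limma with a preset correlation of 0.01, against each vehicle set, and the larger p was adjusted over the 30 lists. The same test with a correlation estimated per list was run beside it. The neutrophil list had 1 tested gene, and the lists of cornea and of mitochondrially encoded genes had 0, so these 3 lists were not tested. The mean log2(FPKM + 1) of the 18 ATF6 targets in each library, called the ATF6 target score, was compared by exact permutation. Exact permutation tests of the means of the other lists, list tests against the vehicle set of the same family, also without each library in turn, 95% intervals and the direct score tests between AA147 and Ceapin-A7 were added after the data were examined.

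The rule for genes named in the text was also fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 FPKM and every compound library on the same side of the vehicle mean, leaving out predicted genes. It took 5 and 5 for AA147 against Ceapin-A7 and for the vehicle sets, 12 genes of the ATF6, IRE1 and PERK pathways and of N-glycosylation, and from each list described up to 4 called members or, where none was called, up to 3 with the highest FPKM. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here.

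The steps were tested on simulated data with the real means and 100 genes changed at each of 2 sizes. The simulated noise was independent between genes, so correlated genes and outlying libraries were not part of the test. With the offset between the vehicle sets built in, a compound against both sets recovered 74 of the 100 genes at 1.5-fold and 86 at 2-fold, with 4 false calls among 164. A compound against the vehicle set of its own family recovered 90 and 94, with 16 false among 200. A direct comparison recovered 88 and 96, with 7 false among 191. For lists with the offset, 0 of 2 were recovered at 1.5-fold, 1 of 2 at 2-fold and 2 of 2 at 3-fold, and against the vehicle set of the own family 2 of 2 at each size. The list sizes above 1.5-fold were added after that size had given 0 of 2.

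The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, median-ratio scaling, quantile normalization, a fit with the compared groups only, array weights, a block for the replicate number, a change of at least 1.5-fold, each vehicle set alone, both sets pooled, an estimated list correlation and leaving out each library in turn. Leaving out libraries 4 and 5 of vehicle set 2, covariates for the lens and Y-linked levels and changes relative to the vehicle set of the own family were added after the data were examined. The median change of all genes lay within 0.05 of 0 on the log2 scale in every comparison, under the deposited scaling and under both alternatives.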

Results

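Retinas of wild-type C57BL/6J mice were profiled by bulk RNA sequencing after an intravitreal injection given at postnatal day 30. The series set out to examine 2 small molecules that act on ATF6, an ER membrane protein whose cleaved form turns on chaperone genes during ER stress. Per the series text, AA147 activates ATF6, Ceapin-A7 inhibits it and tunicamycin, which blocks the first step of N-glycosylation, served as the positive control. Each compound was given at 10 µM in 1 µL. The columns of the compound libraries carry a collection time of 24 h, and those of the vehicle libraries carry no time. The series names collection at 24 h, 3 d and 7 d, so the time of the vehicle libraries is not known. A difference in time between compound and vehicle libraries thus cannot be told apart from an effect of the compound. There were 5 libraries for each compound and 5 in each of 2 vehicle sets. The estimated depth was 15.2 to 24.9 M fragments per library, with the lowest value in Ceapin-A7 library 3 and 18.5 and 17.5 M in tunicamycin libraries 4 and 5. Between 12582 and 12870 genes reached 1 FPKM in a library.

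Tunicamycin was compared with vehicle to see how the positive control moved ER stress genes. Genes of the ER folding machinery rose in the tunicamycin retinas. Hspa5, the main Hsp70 chaperone of the ER, stood at 649 ± 500.0 FPKM (SD, n = 5), against 156 ± 26.0 in vehicle set 1 and 125 ± 24.1 in vehicle set 2. Its log2 change was 1.94 ± 0.24 (SE) against both sets and 2.10 ± 0.28 against vehicle set 2, the set of the same table family (limma adjusted p = 0.000423 for both sets). The SE pools the spread of all groups, and the SD of Hspa5 was largest with tunicamycin, so the SE is too small for that group. Derl3, a component of ER-associated degradation, rose from 0.764 and 0.952 FPKM in the vehicle sets to 30.2 ± 25.9, a log2 change of 3.66 ± 0.31. Sdf2l1, an ER chaperone cofactor, rose by 2.64 ± 0.26, and Manf, an ER-resident protein released under stress, by 1.75 ± 0.23. The changes of Derl3, Sdf2l1 and Manf were 3.59 ± 0.35, 2.75 ± 0.31 and 1.63 ± 0.27 against vehicle set 2 alone. Of 18 ATF6 targets and ER chaperones, 15 rose, 0 fell and 3 did not pass, with 16 past the threshold when adjusted over the list alone. The list rose by a mean of 1.36, or 1.45 against vehicle set 2 (camera adjusted p = 0.000196, and adjusted p = 0.861 with an estimated correlation). The ATF6 target score was 6.69 ± 0.80 in tunicamycin libraries and 5.33 ± 0.14 in the 10 vehicle libraries. That difference had an exact permutation p of 0.000333, the smallest that 3003 arrangements can give. Against vehicle set 2 alone the difference was 1.45, with an exact permutation p of 0.00794, the smallest that 5 against 5 libraries can give. Each of the 5 tunicamycin libraries, at 5.71 to 7.92, lay above all 20 other libraries, at 5.11 to 5.54. The lens gene Cryaa varied widely among the tunicamycin libraries, from 0.97 FPKM in library 3 to 6234 in library 1, where Hspa5 was 229 and 1513 FPKM.

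The lists of the IRE1 and PERK branches of the ER stress response and of N-glycosylation were higher as well, with part of their members past the threshold. Among 16 IRE1-XBP1 targets and translocation genes 12 rose, 0 fell and 4 did not pass, with 14 when adjusted over the list alone, a mean of 0.61, or 0.51 against vehicle set 2 (camera adjusted p = 5.75e-05). Dnajb9, an ER co-chaperone, rose by 1.65 ± 0.20, Sec24d, of the vesicle coat that leaves the ER, by 0.95 ± 0.13, Ero1b, an ER oxidase, by 0.80 ± 0.11 and Ssr3, of the translocon, by 0.79 ± 0.11. The changes of Sec24d, Ero1b and Ssr3 were 0.88 ± 0.16, 0.69 ± 0.13 and 0.61 ± 0.13 against vehicle set 2 alone. Among 24 PERK-ATF4 targets 13 rose, 0 fell and 11 did not pass, with 21 when adjusted over the list alone, a mean of 1.24, or 1.03 against vehicle set 2 (camera adjusted p = 5.75e-05). Chac1, which degrades glutathione, reached 49.7 ± 44.0 FPKM against 2.91 and 9.16 in vehicle sets 1 and 2, a log2 change of 2.69 ± 0.39. Trib3, a pseudokinase induced by ATF4, rose by 2.19 ± 0.26, Mthfd2, a mitochondrial folate enzyme, by 1.79 ± 0.33 and Gdf15, a stress cytokine, by 1.78 ± 0.32. Ddit3, the transcription factor CHOP, rose by 1.17 ± 0.23. Chac1 changed by 2.15 ± 0.45 against vehicle set 2 alone, Trib3 by 1.92 ± 0.30, Mthfd2 by 1.56 ± 0.38, Gdf15 by 1.37 ± 0.37 and Ddit3 by 1.32 ± 0.27. Of 22 N-glycosylation genes 7 rose, 0 fell and 15 did not pass, with 12 when adjusted over the list alone, a mean of 0.29, or 0.27 against vehicle set 2 (camera adjusted p = 0.00909). Stt3a, Ddost and Rpn1, subunits of the oligosaccharyltransferase, rose by 0.68 ± 0.10, 0.59 ± 0.11 and 0.58 ± 0.11. Gfpt1, which opens the hexosamine pathway, rose by 0.42 ± 0.07. These 4 changes against vehicle set 2 alone were 0.64 ± 0.12, 0.65 ± 0.12, 0.55 ± 0.12 and 0.33 ± 0.08. Each of these 3 lists had an adjusted p = 0.861 with an estimated correlation. With vehicle set 2 alone, 13 IRE1, 16 PERK and 12 N-glycosylation genes passed as higher, as did all 18 ATF6 targets, and 0 passed as lower. Libraries 4 and 5 of vehicle set 2 had the highest means of the PERK-ATF4 list among vehicle libraries, 4.84 and 4.99 against 3.87 to 4.09 in the other 8.

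Of the stress sensors and their regulators, Atf6 itself rose by 0.68 ± 0.10 (adjusted p = 0.00725) and Eif2ak3, which encodes PERK, by 0.42 ± 0.08 (adjusted p = 0.0107). Xbp1 rose by 0.96 ± 0.19 and Hsp90b1, the ER form of Hsp90, by 1.02 ± 0.19. Atf6 changed by 0.52 ± 0.11 against vehicle set 2 alone, Eif2ak3 by 0.42 ± 0.10, Xbp1 by 0.90 ± 0.22 and Hsp90b1 by 1.29 ± 0.22. Atf4 differed by 0.63 ± 0.14 (adjusted p = 0.139) and Ern1, which encodes IRE1, by 0.37 ± 0.06 (adjusted p = 0.105), and neither passed. Dpagt1, the enzyme that tunicamycin blocks, differed by 0.53 ± 0.12 (adjusted p = 0.0608, and 0.0116 against vehicle set 2 alone). The differences of Atf6b, Mbtps1 and Mbtps2 were 0.08 ± 0.05, 0.09 ± 0.03 and 0.09 ± 0.05, and none passed (adjusted p = 0.671, 0.261 and 1).

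**Figure D1:**
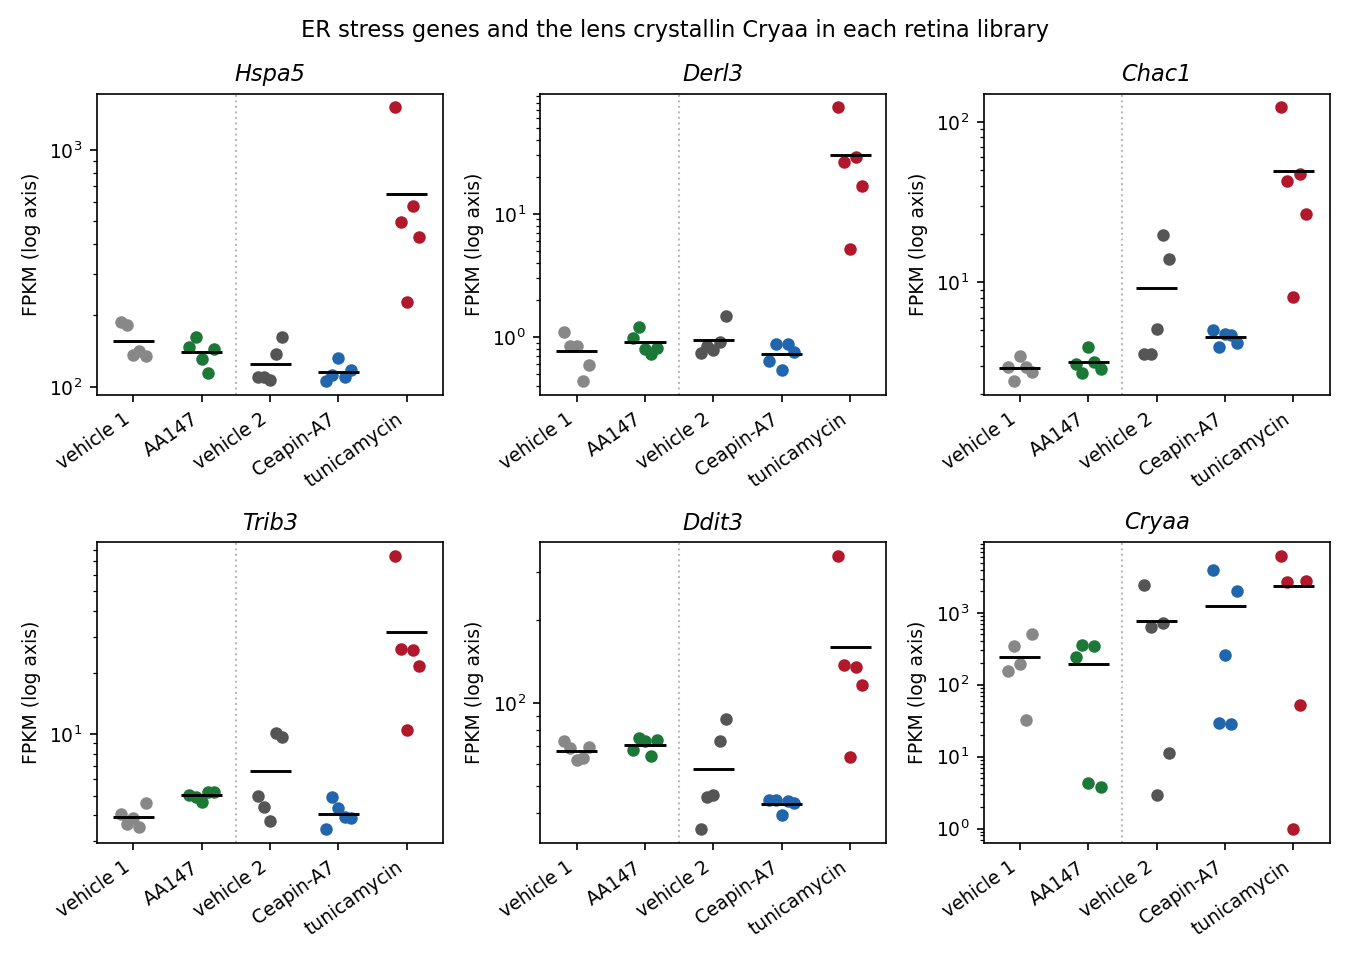
FPKM on a log axis of Hspa5, Derl3, Chac1, Trib3, Ddit3 and the lens gene Cryaa in each of the 25 libraries, with a line at each group mean and a dotted line between the 2 table families. Hspa5 reached 1513 FPKM in tunicamycin library 1, and Cryaa spanned 0.97 to 6234 FPKM within that group.

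Of 23 tested markers of endothelium and of pericytes and smooth muscle, 12 fell in the tunicamycin retinas, 1 rose and 10 did not pass. Ly6c1, an endothelial surface protein, fell by 2.23 ± 0.11 on the log2 scale, from 17.6 and 20.1 FPKM in the vehicle sets to 3.30 ± 1.04. Cldn5, the tight junction protein of the blood-retina barrier, fell by 1.27 ± 0.10, and Tek, the angiopoietin receptor, by 0.64 ± 0.06. Egfl7, a protein secreted by endothelium, rose by 0.80 ± 0.07. Of 13 endothelial genes 7 fell, 1 rose and 5 did not pass, with 7 and 2 when adjusted over the list alone, a mean of -0.44, or -0.43 against vehicle set 2 (camera adjusted p = 0.00209). Rgs5, a pericyte regulator of G-protein signalling, fell by 1.64 ± 0.07 to 5.30 ± 0.87 FPKM. Higd1b, Notch3 and Abcc9, which also mark pericytes, fell by 1.27 ± 0.16, 0.73 ± 0.07 and 0.72 ± 0.06. Of 10 pericyte and smooth muscle genes 5 fell, 0 rose and 5 did not pass, with 6 when adjusted over the list alone, a mean of -0.65, or -0.58 against vehicle set 2 (camera adjusted p = 0.000183). Both lists had an adjusted p = 0.861 with an estimated correlation. The pericyte list had 0.0499 with an estimated correlation against vehicle set 2 alone. In that comparison 7 endothelial genes passed as lower and 2 as higher, and 5 pericyte genes as lower and 0 as higher. All 5 tunicamycin libraries lay below the 20 others in both list means. Edn1, a vasoconstrictor peptide, rose by 2.29 ± 0.08 to 11.3 ± 1.51 FPKM, and Apln, an angiogenic peptide, rose by 1.85 ± 0.12. Ly6a, an endothelial surface protein, fell by 1.67 ± 0.13, and Mgp, a matrix inhibitor of calcification, by 2.09 ± 0.29. Ly6c1 changed by -2.31 ± 0.13 against vehicle set 2 alone, Cldn5 by -1.32 ± 0.12, Rgs5 by -1.57 ± 0.08, Edn1 by 2.26 ± 0.09 and Ly6a by -1.89 ± 0.15.

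**Figure D2:**
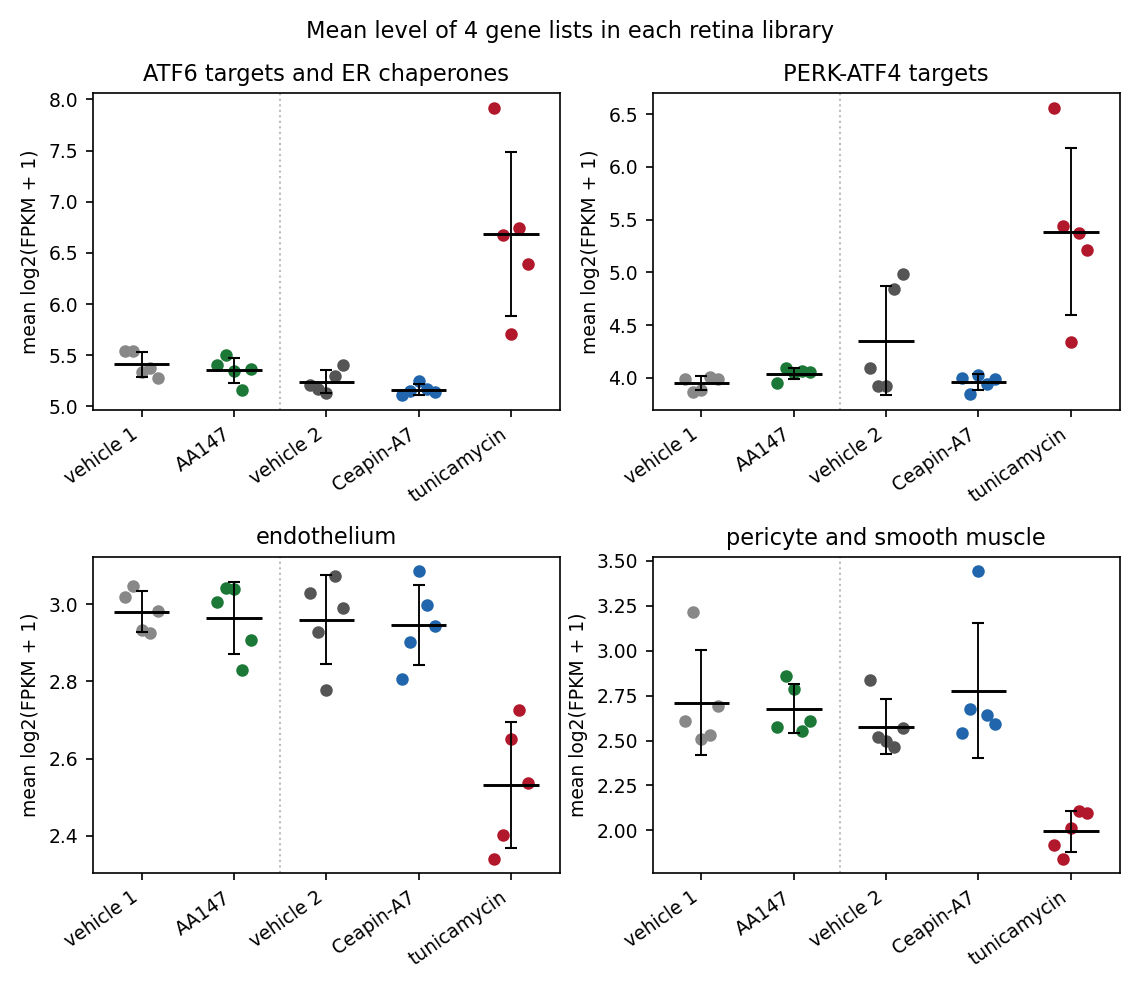
Mean log2(FPKM + 1) of 4 gene lists in each of the 25 libraries, with the mean and SD of each group. The tunicamycin libraries lay at 5.71 to 7.92 for the ATF6 targets, above the 20 others, and at 1.84 to 2.11 for pericytes, below them.

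Sterol synthesis genes and amacrine markers were lower as lists. Of 18 sterol genes 5 fell, 0 rose and 13 did not pass, with 12 when adjusted over the list alone, a mean of -0.25, or -0.28 against vehicle set 2 (camera adjusted p = 0.0297). Hmgcs1, an enzyme of cholesterol synthesis, fell by 0.40 ± 0.06. Of 15 amacrine markers 0 passed, also when adjusted over the list alone, with a mean of -0.17, or -0.13 against vehicle set 2 (camera adjusted p = 0.0123). Among the highest expressed of them were the calcium-binding protein gene Calb2 at -0.21 ± 0.09 and Gad1, which makes GABA, at -0.21 ± 0.06. Against vehicle set 2 the amacrine mean moved to -0.07 without tunicamycin library 1. With all libraries 13 sterol genes and 1 amacrine gene passed as lower there, and 0 as higher. Both lists had an adjusted p = 0.861 with an estimated correlation. In exact permutation tests of list means, chosen after the values were seen and adjusted over 30 lists, the ATF6, IRE1, N-glycosylation, endothelial and pericyte lists had adjusted p = 0.002. The sterol list had 0.005, the PERK list 0.00856 and the amacrine list 0.045. The heat shock and immediate early lists, which did not pass in camera, had 0.040 each. Against vehicle set 2 the first 6 of these lists had an adjusted exact permutation p of 0.0397, the PERK list 0.179 and the amacrine list 0.403 (unadjusted 0.175). The heat shock and immediate early lists had an adjusted exact permutation p of 0.368 each there.

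The other 22 lists tested did not pass for tunicamycin against both vehicle sets, with camera adjusted p from 0.0655 to 1, and 6 of them passed against vehicle set 2 alone. Pigment epithelium genes were lower there in 10 of 12 members (adjusted p = 0.00093), heat shock genes in 11 of 14 (0.00093), bipolar genes in 13 of 16 (0.0157), ganglion cell genes in 14 of 18 (0.0179) and gliosis genes in 17 of 19 (0.0179). Sex-linked genes were higher in 4 of 4 (0.00382), and of the 5 libraries of vehicle set 2, 4 had Ddx3y under 1 FPKM. These 6 lists had adjusted p of 0.362 to 0.707 with an estimated correlation. Without libraries 4 and 5 of vehicle set 2 the heat shock, ganglion cell and gliosis lists no longer passed (adjusted p = 0.0766, 0.201 and 0.726), while 4 others did: rod genes and Muller glia genes as lower (1.72e-13 and 0.000751) and immediate early and apoptosis genes as higher (0.0111 and 0.0222). Of the 15 lists that then passed, 11 were among the 14 that passed with all libraries. Single libraries mattered as well. The bipolar mean of -0.09 moved to -0.03 without tunicamycin library 1 (adjusted p = 0.181) and did not pass without library 2 or 3 of vehicle set 2 (adjusted p = 0.0826 and 0.0611). The ganglion cell mean of -0.08 moved to -0.02 without library 5 of vehicle set 2 (adjusted p = 0.341) and to -0.05 without tunicamycin library 1 (adjusted p = 0.0365). The gliosis mean of -0.32 moved to -0.08 without library 4 of vehicle set 2 (adjusted p = 0.286), to -0.18 without tunicamycin library 4 (adjusted p = 0.191) and to -0.53 without library 3 of vehicle set 2. The heat shock mean of -0.16 moved to -0.09 without library 5 of vehicle set 2 (adjusted p = 0.0175). Of 14 heat shock genes Hspa1b and Hspa1a, cytosolic Hsp70 genes, fell by 0.96 ± 0.15 and 0.76 ± 0.11, with 4 down when adjusted over the list alone. Hmox1, which encodes heme oxygenase, was the 1 of 19 NRF2 genes to rise, by 1.33 ± 0.25. Ccn1, a matrix-associated growth factor, and Dusp1, a phosphatase, were the 2 of 12 immediate early genes to rise, by 1.48 ± 0.19 and 0.52 ± 0.11. Gap43, a growth cone protein, was the 1 of 10 axon injury genes to fall, by 0.48 ± 0.09. Ttr, the transthyretin gene of pigment epithelium, was the 1 of 12 pigment epithelium genes to fall against both sets, by 2.67 ± 0.36 to 14.8 ± 7.65 FPKM. Of these 12, 5 passed as lower and 0 as higher against vehicle set 2 alone. Hspa1b changed by -0.75 ± 0.18 against vehicle set 2 alone, Hspa1a by -0.54 ± 0.12, Hmox1 by 1.18 ± 0.29, Ccn1 by 1.36 ± 0.22, Dusp1 by 0.48 ± 0.13, Gap43 by -0.37 ± 0.10 and Ttr by -3.02 ± 0.41. Of the 13 apoptosis genes and 7 cytokine genes 0 passed, with 2 and 1 up when adjusted over the list alone. In the lists of rods (22 genes), cones (13), bipolar cells (16), horizontal cells (7), ganglion cells (18), Muller glia (17), gliosis (19), microglia (17), interferon (20), lens (19), fibroblasts (11), erythrocytes (5), the clock (16), ribosomal proteins (27) and sex-linked genes (4), 0 genes passed by either adjustment against both vehicle sets. With vehicle set 2 alone, 4 sex-linked, 2 clock, 2 ribosomal and 1 cone gene passed as higher, and 1 clock, 1 bipolar and 1 horizontal gene as lower. The lens list differed by 1.02 and the pigment epithelium list by -0.64, means taken over libraries that varied widely.

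In all, 611 of 13117 genes passed for tunicamycin in limma, 440 higher and 171 lower. The remaining genes of largest change were Pycr1, an enzyme of proline synthesis, which rose by 1.91 ± 0.33, and Pltp, Pglyrp1, Srarp, Epas1 and Slc6a20a. Pltp, a phospholipid transfer protein, fell by 1.78 ± 0.14, the innate immune gene Pglyrp1 by 1.41 ± 0.15, Srarp by 1.22 ± 0.12 and the proline transporter Slc6a20a by 1.18 ± 0.22. Pycr1 changed by 1.81 ± 0.38 against vehicle set 2 alone, Pltp by -1.80 ± 0.16, Pglyrp1 by -1.59 ± 0.18, Srarp by -1.27 ± 0.14 and Slc6a20a by -1.32 ± 0.25. Epas1, which encodes the hypoxia factor HIF-2α, differed between the vehicle sets, at 43.8 and 15.9 FPKM, and was 11.1 in tunicamycin, a log2 change of -0.47 ± 0.11 against vehicle set 2. The split between higher and lower depended on scaling: 301 higher and 291 lower with median-ratio scaling, and 314 and 296 with quantile normalization. The count was 1141 (773 higher, 368 lower) against vehicle set 2 alone, 349 without tunicamycin library 1, 1146 without tunicamycin library 3, 219 with the Y-linked level as a covariate and 177 with the compared groups only. Chac1, Pycr1, Mthfd2, Gdf15, Epas1 and Slc6a20a lost the call in at least 1 of 28 alternatives, and of the pathway genes Ddit3 kept it in 22 of 28, Atf6 and Xbp1 in 26, Eif2ak3 in 27 and Hsp90b1 in 13. Leaving out 1 library ended the call of Ddit3 (tunicamycin 1 or 4, vehicle set 1 library 3 or 4), Mthfd2 (vehicle set 2 library 1 or 3), Slc6a20a (vehicle set 1 library 5) and Gdf15 (tunicamycin 1, 2 or 5, vehicle set 2 library 1, 2 or 3). It ended that of Hsp90b1 for tunicamycin 2 or 4 and for each vehicle library except library 2 of either set. Of the pathway genes not called, Atf4 passed in 6 of the 28 alternatives, Ern1 and Dpagt1 in 5, Mbtps1 in 2, Mbtps2 in 1 and Atf6b in 0. All of Atf4, Ern1 and Dpagt1 passed without tunicamycin 3, Atf4 also without library 5 of vehicle set 2 and Ern1 also without its library 4. Y-linked Ddx3y lay under 1 FPKM in 4 of 5 libraries of vehicle set 2 and in 0 of 5 tunicamycin libraries.

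AA147 was compared with vehicle to see whether ATF6 targets rose without tunicamycin. Hspa5 stood at a log2 difference of -0.15 from vehicle set 1, the set of the same table family, with a 95% interval from -0.73 to 0.43. Of the 18 ATF6 targets 14 were lower and 4 higher than in vehicle set 1, 0 passed by either adjustment, and 9 had a 95% interval within 1.5-fold. The ATF6 target score was 5.35 ± 0.12 (SD, n = 5), a difference of 0.03 from both vehicle sets (exact permutation p = 0.732). It was -0.06 against vehicle set 1 (exact permutation p = 0.484) and 0.11 against vehicle set 2 (exact permutation p = 0.175). The difference from vehicle set 1 moved to -0.01 without AA147 library 4, to -0.03 without library 1 or 2 of vehicle set 1, and to -0.09 without AA147 library 2 or library 5 of vehicle set 1. Without AA147 library 2 the difference from both sets turned to -0.0091. Across all genes 0 passed in limma for AA147, with 81 at an unadjusted p under 0.05, and 0 against vehicle set 1 alone, with 246. The count was 6016 against vehicle set 2, which belongs to the other family, 1 with the Y-linked level as a covariate and 1 without AA147 library 5. The smallest p belonged to Hpcal1, a neuronal calcium sensor, at 0.22 ± 0.04 against vehicle set 1 (adjusted p = 0.571). Of the 13117 intervals against vehicle set 1, 12700 (96.8%) lay within 1.5-fold, with a median half-width of 0.136 on the log2 scale. A missed threshold does not show that AA147 and vehicle retinas were alike.

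Of the 30 lists, 0 passed for AA147 against both vehicle sets in camera, each with an adjusted p of 1, and 6 passed against vehicle set 1 alone. Interferon and antigen presentation genes were higher in all 20 members, with a mean of 0.25 (adjusted p = 1.85e-05, and adjusted p = 0.940 with an estimated correlation). Without AA147 library 2 the mean moved to 0.13 and the list no longer passed (adjusted p = 0.0660). The highest expressed of them, the class I genes H2-D1, B2m and H2-K1, differed by 0.08, 0.04 and 0.03. Sterol genes were lower in 17 of 18 members, with a mean of -0.08 (adjusted p = 2.99e-06, and adjusted p = 0.797 with an estimated correlation), with Hmgcs1 at -0.06, Fdps, a prenyl synthase, at -0.003 and Insig1, a regulator of sterol synthesis, at -0.08. Ribosomal protein genes were higher in 23 of 27, with a mean of 0.06 (adjusted p = 0.00151). That list did not pass without library 2 or 3 of vehicle set 1 or AA147 library 2 (means of 0.04, 0.04 and 0.04, adjusted p = 0.295, 0.0733 and 0.114), and its mean was 0.09 without AA147 library 1. Rod genes were lower in 13 of 22, with a mean of -0.03 (adjusted p = 0.0454). They did not pass without library 2 or 5 of vehicle set 1 or AA147 library 1, 2 or 3, with means from -0.03 to -0.02 and adjusted p of at least 0.0534. Lens genes were lower in 19 of 19, with a mean of -1.11 (adjusted p = 0.000399). That mean moved to -0.40 without AA147 library 5, -0.51 without AA147 library 3 and -0.81 without library 5 of vehicle set 1, and the list then did not pass (adjusted p = 0.145, 0.100 and 0.0880). Sex-linked genes were lower in 4 of 4, with a mean of -1.43 (adjusted p = 0.000399), which moved to -0.89 and -0.87 without AA147 library 4 or 5. The ribosomal, rod, lens and sex-linked lists had adjusted p of 0.940, 0.940, 0.940 and 0.797 with an estimated correlation. Ddx3y lay under 1 FPKM in 2 of 5 AA147 libraries and 0 of 5 of vehicle set 1. Exact permutation of the list means gave adjusted p of at least 0.952 against vehicle set 1.

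Ceapin-A7 was compared with vehicle to see whether ATF6 targets fell. Hspa5 differed by -0.10 from vehicle set 2, the set of its own family, with a 95% interval from -0.68 to 0.48. All 18 ATF6 targets were lower than in vehicle set 2, 0 passed by either adjustment, and 11 had a 95% interval within 1.5-fold. The ATF6 target score was 5.16 ± 0.05 (SD, n = 5), which fell by 0.16 against both vehicle sets (exact permutation p = 0.0290, adjusted over 3 compounds 0.0435). All 5 libraries lay below the vehicle mean of 5.33. Libraries 1 to 4 of vehicle set 2 lay below 5.33 as well, and only library 5 of that set lay above it. A position below 5.33 thus does not set Ceapin-A7 apart from the vehicle set of its own family. The score difference was -0.08 against vehicle set 2 alone (exact permutation p = 0.206) and -0.25 against vehicle set 1 (exact permutation p = 0.00794). The difference from vehicle set 2 moved to -0.04 without its library 5 and to -0.0040 without its libraries 4 and 5. For the ATF6 target score, Ceapin-A7 no longer passed without Ceapin-A7 library 1, 2 or 5 (exact permutation p up to 0.0639), without libraries 4 and 5 of vehicle set 2 (exact permutation p = 0.0559) or with a block for the replicate number (exact permutation p = 0.0658). Across all genes, the number of genes changed by Ceapin-A7 was 0 in limma, with 862 at an unadjusted p under 0.05, and 0 against vehicle set 2 alone, with 1615. The count was 6676 against vehicle set 1, of the other family, 1327 with the sets pooled and up to 6 without library 2 or 3 of vehicle set 2 or library 2 of vehicle set 1. The smallest p belonged to Shisal2b, at 2.19 FPKM against 0.412 and 0.86 in the vehicle sets and a log2 difference of 1.00 ± 0.12 (adjusted p = 0.0649). Of the intervals against vehicle set 2, 12479 (95.1%) lay within 1.5-fold.

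Of the 30 lists, 0 passed for Ceapin-A7 against both vehicle sets in camera, with the smallest adjusted p for gliosis (0.648), and 1 bipolar gene passed when adjusted over its list alone, as lower. There were 12 lists that passed against vehicle set 2 alone. Reactive gliosis genes were lower in all 19 members, with a mean of -0.70 (adjusted p = 4.96e-09, and adjusted p = 0.393 with an estimated correlation). The mean was -0.47 without library 4 of vehicle set 2 and -0.38 without its libraries 4 and 5. Of these, the intermediate filament gene Vim was at 121 ± 17.2 FPKM against 215 ± 100.3, a log2 difference of -0.70 ± 0.23 (adjusted p = 0.304), Cp, which encodes ceruloplasmin, at -0.49 and Stat3 at -0.67. Immediate early genes were lower in 11 of 12, with a mean of -0.35 (adjusted p = 4.23e-05), and sterol genes in 15 of 18, with a mean of -0.09 (adjusted p = 0.000534). Rod genes were higher in 21 of 22 (adjusted p = 1.2e-08), cone genes in 12 of 13 (4.4e-05) and ribosomal genes in 23 of 27 (0.018). With quantile normalization the rod mean moved from 0.17 to 0.06, the cone mean from 0.17 to 0.15 and the ribosomal mean from 0.05 to -0.01. PERK-ATF4 targets were lower in 23 of 24 (0.000431), axon injury genes in 10 of 10 (0.000213) and apoptosis genes in 10 of 13 (0.0359). Muller glia genes were higher in 12 of 17 (0.0359), pericyte genes in 9 of 10 (0.0359) and sex-linked genes in 4 of 4 (0.0246). With an estimated correlation the 12 lists had adjusted p of 0.393 to 0.855. Exact permutation of the list means against vehicle set 2 gave adjusted p of at least 0.238, with 0.417 for gliosis and 0.429 for PERK-ATF4 and rod genes. Without libraries 4 and 5 of vehicle set 2, which held the highest PERK-ATF4 levels, 5 of the 12 passed: gliosis, immediate early, sterol, ribosomal and sex-linked genes. The means of PERK-ATF4, rod and axon injury genes then moved from -0.39 to -0.02, from 0.17 to 0.03 and from -0.27 to -0.06. Without library 5 of vehicle set 2 alone the PERK-ATF4 mean was -0.23, and without library 4 the axon injury mean was -0.17. The pericyte mean of 0.20 moved to 0.03 without Ceapin-A7 library 3 (adjusted p = 0.545) and the list also did not pass without library 2, 3 or 4 of vehicle set 2. The ribosomal mean moved to 0.02 without library 1 of vehicle set 2 (adjusted p = 0.294) and to 0.07 without library 2, and the list did not pass without Ceapin-A7 library 2 (adjusted p = 0.0575). The apoptosis list (mean -0.16) did not pass without Ceapin-A7 library 3 or 5 or library 3, 4 or 5 of vehicle set 2, with means from -0.19 to -0.09. The Muller glia list (mean 0.14) did not pass without Ceapin-A7 library 1, 3 or 5 or library 2, 4 or 5 of vehicle set 2, with means from 0.09 to 0.14. The sex-linked list (mean 1.58) did not pass without Ceapin-A7 library 1, 2 or 3 or library 2 or 3 of vehicle set 2, with means from 1.18 to 1.39.

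AA147 and Ceapin-A7 were compared directly as the activator and the inhibitor at the same dose. The largest differences that the naming rule took were in Zbed6, Glra1, Sntb2, Lnpep and Zfp973, lower with AA147, and Tnnt2, Stxbp4, Epas1, Vmn1r58 and Rps15a-ps5, higher. Zbed6, a zinc finger gene, was 0.368 FPKM with AA147 and 12.7 with Ceapin-A7, a log2 difference of -3.32 ± 0.06, and the vehicle sets of the 2 table families held 0.38 and 13.1. Glra1, a glycine receptor subunit, was 0.562 against 7.25 FPKM, with 0.518 and 6.97 in the vehicle sets. Stxbp4 was 24.7 against 6.37 FPKM, with 25.8 and 6.16 in the vehicle sets. In limma 6697 genes passed, 3091 higher with AA147 and 3606 lower, and 0 when each compound was taken relative to the vehicle set of its own family, with 882 at an unadjusted p under 0.05. This balance of higher and lower genes also depended on scaling: 3350 higher and 3372 lower with median-ratio scaling, and 3419 and 3255 with quantile normalization. The ATF6 target score was 0.19 higher with AA147 (exact permutation p = 0.0238). Relative to the own vehicle sets it differed by 0.02 (exact permutation p = 0.846 over 63504 arrangements).

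The vehicle sets differed from each other at 6145 genes, 3455 higher in vehicle set 2 and 2690 lower. The majority direction turned with scaling: 3087 higher and 3144 lower with median-ratio scaling, and 3036 and 3182 with quantile normalization. Sntb2, a syntrophin, rose from 2.32 FPKM in set 1 to 15.3 in set 2, Lnpep, an aminopeptidase, from 0.724 to 6.72, and Sesn3, a sestrin, differed by 1.98 ± 0.07 on the log2 scale. Stxbp4, Vmn1r58, H2bc4, Psg16 and Tmem45b, in contrast, were lower in set 2, with log2 differences of -1.90, -1.82, -1.50, -1.47 and -1.44. The predicted gene LOC118568718, outside the naming rule and chosen after its values were seen, was at 1162 FPKM in vehicle set 1, 1081 with AA147, and 5.28 to 7.28 in the 3 other groups. Of the 30 lists 0 passed between the vehicle sets, the smallest p being that of the rod genes (0.00712, adjusted 0.213). Across genes, the difference between AA147 and Ceapin-A7 followed that between vehicle set 1 and vehicle set 2, with a slope of 0.873, in comparisons that share no library. The median correlation between libraries was 0.986 within a table family and 0.973 between families.

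**Figure D3:**
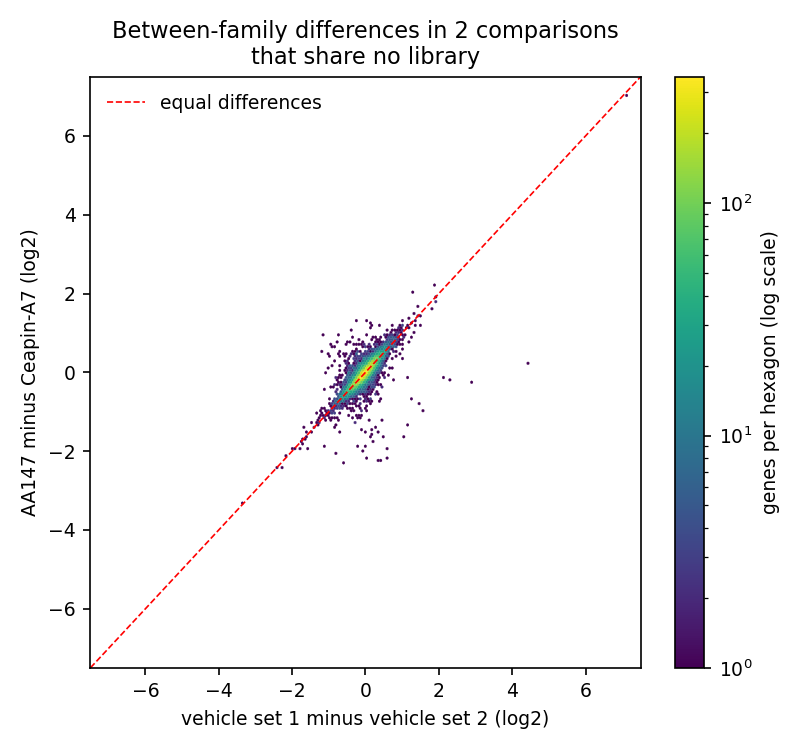
Log2 difference of vehicle set 1 minus vehicle set 2 (x axis) against AA147 minus Ceapin-A7 (y axis) for 13117 genes, shaded by the number of genes per hexagon on a log scale, with the line of equal differences dashed. Most genes far from 0 lay along the line, with a slope of 0.873.

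Tunicamycin and Ceapin-A7 belonged to the same table family and were compared directly, to see the positive control beside the inhibitor without the offset between families. Hspa5 was at 649 FPKM with tunicamycin and 115 with Ceapin-A7 (limma adjusted p = 1.8e-05). Derl3 was 3.75 ± 0.35 higher on the log2 scale and Edn1 2.33 ± 0.09, while Ly6c1 differed by -2.34 ± 0.13 and Rgs5 by -1.73 ± 0.08. In limma the genes differing between tunicamycin and Ceapin-A7 numbered 1746, 1158 higher with tunicamycin and 588 lower, and 465 of the 611 genes called for tunicamycin were among them in the same direction. The split was 921 and 839 with median-ratio scaling and 824 and 721 with quantile normalization. The count was 925 without tunicamycin library 1, 2874 without library 3 and 613 with the compared groups only. Tunicamycin and AA147, each relative to the vehicle set of its own family, differed at 136 genes, 84 higher with tunicamycin. Among these were Hspa5 at 2.25 ± 0.40, Derl3 at 3.47 ± 0.50, Edn1 at 2.16 ± 0.13, Rgs5 at -1.66 ± 0.12 and Ly6c1 at -2.38 ± 0.18.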

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

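The tests of separate preparation, of the sex mix, of genes taking most of the signal of vascular cell loss and of pigment epithelium over all 23 vascular genes were chosen after the results were seen, and the tests of GC content and length, lens and pigment epithelium over the called vascular genes before theirs were seen.

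In 245 groups of 5 values, taken from 48 named genes and the ATF6 target score in 5 groups, 1 library stood apart from the other 4 in 16, where chance gives about 12.25. Among vehicle libraries, Derl3 was 1.48 FPKM in library 5 of set 2 (others 0.74 to 0.92), and Apln 0.89 in library 5 of set 1 (0.33 to 0.47). Slc6a20a was 3.94 in library 5 of set 1 (1.16 to 1.68), and Ly6c1 14.83 in library 3 of set 2 (20.42 to 23.19). Library 5 of set 2 also had Sntb2 at 13.62 (15.5 to 16.03) and Lnpep at 4.35 (6.73 to 7.79). Among Ceapin-A7 libraries, Ly6c1 was 16.55 in library 1 (20.55 to 22.09) and Atf4 225.83 in the same library (205.63 to 210.47). Library 3 had Xbp1 at 49.45 (42.22 to 44.2) and Ddit3 at 39.31 (43.2 to 44.47), library 2 had Stxbp4 at 6.96 (6.12 to 6.34) and library 4 had Lnpep at 5.99 (6.6 to 6.85). Among AA147 libraries, Rps15a-ps5 was 43.17 in library 5 (31.82 to 34.04), Sntb2 2.44 in library 1 (2.13 to 2.16) and Zfp973 was listed at 0 in library 4 (1.56 to 1.87). Tunicamycin library 1 had Psg16 at 6.06 (7.11 to 7.5).

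The vehicle sets differed at 6145 genes although both carry the same treatment label. A different sex mix of the mice is argued against as the whole cause, since AA147 and Ceapin-A7, with 2 libraries each that lacked Y-linked transcripts, differed at 6697 genes. A GC or length trend between libraries is argued against as well, since 5429 genes differed after its removal, of 5968 before it among the 12799 genes with an annotated length. Separate preparation or quantification of the table families remains a candidate explanation: differences that share no library correlated at r = 0.806 across genes, which are not independent replicates. Which step differed was not tested, and the labels give no batch and no collection time for the vehicle libraries.

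ER stress genes were higher in tunicamycin libraries, which also varied widely in lens transcripts. Lens tissue that raises the score alike in all groups is argued against as the whole cause. The ATF6 target score difference was 1.30 ± 0.19 (SE) with the lens level as a covariate and 1.36 without it. That SE pools the spread of all groups. The score SD was 0.80 with tunicamycin and 0.05 to 0.12 in the other groups, so the SE is too small. The covariate had 1 slope for all groups, so it cannot tell whether lens tissue exposed to tunicamycin added to the rise. In tunicamycin libraries 1 to 5 the lens level was 8.69, 7.82, 0.49, 3.44 and 6.96, and the score 7.92, 6.68, 5.71, 6.74 and 6.39. The lens list had 19 of 19 members expressed in these retinas, although the protocol removes the lens, and Ceapin-A7 library 1 had Cryaa at 3973 FPKM with Hspa5 at 106. A few genes taking most of the signal is argued against too, since median-ratio scaling left the score difference at 1.33. No vehicle set matched tunicamycin in both table family and Y-linked transcripts. Ddx3y lay under 1 FPKM in 4 of 5 libraries of vehicle set 2 and in 0 of 5 of vehicle set 1 and of tunicamycin. With the Y-linked covariate 219 genes passed, with Hspa5 and Derl3 but without Chac1, Atf6, Xbp1, Ddit3 and Hsp90b1. A different sex mix as the whole cause of the higher ATF6 target score is argued against. The 20 other libraries, with or without Y-linked transcripts, scored 5.11 to 5.54, and the tunicamycin libraries 5.71 to 7.92. Against vehicle set 1, of the other table family but also with Y-linked transcripts throughout, the score difference was 1.27. For the single genes that lost the call with the Y-linked covariate, the sex mix was not tested as the cause. A response to tunicamycin stays open as a biological explanation and may account for the pattern, though the libraries may not be separate animals.

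Vascular marker genes were lower in tunicamycin libraries. Of 13 endothelial genes, 7 had a 95% interval apart from the list's median of -0.36, 3 above it and 4 below. The log2(FPKM + 1) scale understates the change of low genes, so unequal falls alone do not decide on a uniform loss of endothelial cells. That loss as the whole cause is argued against by the 2 of 13 genes that passed as higher against vehicle set 2. Less pigment epithelium and choroid left on the retina, a list with 12 of 14 genes expressed here, is argued against as the whole cause by its level as a covariate. Over all 23 tested vascular genes the mean change against vehicle set 2 was -0.41 ± 0.09 (SE) with it and -0.50 ± 0.09 without it, and over the 12 of 13 called genes that fell, leaving out Egfl7, which rose, -0.89 ± 0.06 and -0.91 ± 0.05. A change in transcription within vascular cells, alone or with some loss of them, may explain the pattern and was not tested.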

How the results depend on the processing

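Leaving out libraries 4 and 5 of vehicle set 2, the lens and Y-linked covariates, changes relative to the own vehicle set and all settings of tunicamycin against Ceapin-A7 were chosen after the results were seen, and the other alternatives before.

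For genes changed by tunicamycin, 8 of 14 alternatives stayed within 1.5 times 611. The others gave 177 with the compared groups only (177 shared with the 611), 180 at 1.5-fold or more, 7381 against vehicle set 1, 1141 against set 2, 3991 with the sets pooled and 219 with the Y-linked covariate (209 shared). The lens covariate gave 505, of which 495 were shared, and leaving out the 2 vehicle libraries 574, of which 411 were shared. Leaving out 1 library gave 349 (without tunicamycin 1) to 1146 (without tunicamycin 3). For gene lists changed by tunicamycin, 8 became 0 with an estimated correlation, 14 against vehicle set 2 and 15 with the sets pooled, and 8 to 11 without 1 library. For genes changed by AA147, 0 became 6016 against vehicle set 2 and 1 with the Y-linked covariate, and 0 to 1 without 1 library (AA147 5). For gene lists changed by AA147, 0 became 6 against vehicle set 1, and stayed 0 without any 1 library. For genes changed by Ceapin-A7, 0 became 6676 against vehicle set 1 and 1327 with the sets pooled, and 0 to 6 without 1 library (the most without vehicle set 2 library 2). For gene lists changed by Ceapin-A7, 0 became 12 against vehicle set 2 and 1 with the sets pooled, and stayed 0 without any 1 library. The genes differing between AA147 and Ceapin-A7 numbered 685 at 1.5-fold or more, 0 relative to the own vehicle sets and 6229 to 6461 without 1 library. The genes differing between the vehicle sets numbered 557 at 1.5-fold or more and 5721 to 6012 without 1 library. The genes differing between tunicamycin and Ceapin-A7 numbered 613 with the compared groups only, 234 at 1.5-fold or more and 925 (without tunicamycin 1) to 2874 (without tunicamycin 3). For ATF6 target score, tunicamycin, all 8 alternatives stayed past the threshold at 1.27 to 1.45, and 1.05 to 1.60 without 1 library. For ATF6 target score, AA147, the difference reversed to -0.058 against vehicle set 1 and to -0.0091 without AA147 library 2, and ran from -0.0091 to 0.074 without 1 library. For ATF6 target score, Ceapin-A7, the test no longer passed against vehicle set 2 (-0.078, exact permutation p = 0.206) or without vehicle set 2 libraries 4 and 5 (-0.16, exact permutation p = 0.0559). It ran from -0.18 to -0.14 without 1 library and did not pass without Ceapin-A7 library 1, 2 or 5. The larger counts across table families go with the offset between the families, the fold limit leaves fewer genes by construction, and otherwise the cause was not tested.

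The replicate numbers did not pair the libraries: same-number correlations ran from -0.49 to 0.60, and in 0 of 10 pairs of groups were all above 0.1. With a block for the replicate number, the genes changed by tunicamycin were 591, with 8 lists, and 0 genes and 0 lists changed for AA147 and Ceapin-A7. The genes differing between AA147 and Ceapin-A7 were 6660, the genes differing between the vehicle sets 6119 and the genes differing between tunicamycin and Ceapin-A7 1727. The blocked test of the ATF6 target score, Ceapin-A7 (-0.16) had an exact permutation p of 0.0658, which ended its call, and the block ended no other call among these. Ern1 gained a call for tunicamycin with the block. The form of that score test was changed after a first form, whose smallest possible p exceeded 0.05, had been run. Of the 24 tunicamycin genes named by size, 18 stayed past the threshold in all 28 alternatives. At the estimated depth of 15.2 to 24.9 M fragments, low genes rest on few fragments, and the added 1 FPKM shrinks their changes.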

Other observations

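The vascular genes outside the naming rule, the exact permutation tests of list means, the list tests against the own vehicle set and the counts over other splits were chosen after the results were seen.

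A few vascular genes outside the naming rule, chosen after their values were seen, are given here for tunicamycin against both vehicle sets. Angpt2, an angiopoietin that destabilises vessels, rose by 1.07 ± 0.07 on the log2 scale, Robo4, an endothelial guidance receptor, by 1.01 ± 0.07 and Vegfa, the vascular growth factor, by 0.69 ± 0.09 (limma adjusted p = 9.79e-08, 2.42e-08 and 0.000719). Of the pan-endothelial genes, Pecam1 differed by -0.17 ± 0.07 (adjusted p = 0.712) and the cadherin gene Cdh5 by 0.40 ± 0.09 (adjusted p = 0.0729), and neither passed. Against vehicle set 2 alone Cdh5 differed by 0.48 ± 0.10 and passed (adjusted p = 0.00470), and Pecam1 by -0.10 ± 0.08 did not (adjusted p = 0.478).

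Libraries 4 and 5 of vehicle set 2 held the highest PERK-ATF4 list means of the vehicle libraries. Chac1 was 19.7 and 13.9 FPKM there, Trib3 10.1 and 9.67, and Atf4 294 and 356. Without these libraries, tunicamycin differed from vehicle set 2 at 1031 genes, 829 higher and 202 lower, and Ceapin-A7 at 0 in limma, with 441 at an unadjusted p under 0.05.

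Gm20594, a predicted gene chosen after its values were seen, was listed only in the tables of vehicle set 1 and AA147. It was at 476 ± 31.1 FPKM in vehicle set 1 and 487 ± 53.6 with AA147 (SD, n = 5, exact permutation p = 0.730). The genes with every compound library above, or every one below, all 10 vehicle libraries numbered 343 for tunicamycin, 19 for AA147 and 93 for Ceapin-A7. Chance gives 8.74 (0.0666%) if the libraries of both table families are exchangeable, which the difference between the vehicle sets rules out, so no excess over chance is shown by these counts. Of the 343, 273 were among the 611 called.

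Each count was set against 100 splits of the same libraries into groups of the same sizes, the real split included. For the 611 genes of tunicamycin, 3 of the 100 splits, the real one included, gave as many. The highest other split gave 2076, more than the real one. These splits mix the table families, whose vehicle sets differed at 6145 genes. The libraries are thus not exchangeable, and the share does not decide on chance. Which libraries the split with 2076 grouped was not recorded. That count thus does not tell a structure of the samples from a split that keeps most tunicamycin libraries together. Chance cannot be excluded by the splits for the 8 lists of tunicamycin, where 17 splits gave as many and the highest other gave 13, in splits that mix the table families. Within the family of vehicle set 2, exact permutation of the list means gave an adjusted p of 0.0397 for 6 of these lists, taken 1 by 1. The splits say nothing on chance for AA147 or Ceapin-A7, since each of the 100 splits must give at least the real 0 genes and 0 lists. The highest others were 1090 genes and 9 lists for AA147, and 1061 and 10 for Ceapin-A7. For AA147 against Ceapin-A7, 1 split, the real one, gave 6697 and the highest other 1935. Only the real split parts the table families here. It thus excludes a chance split of these libraries for the offset between families, and says nothing on the compounds. Relative to the own vehicle sets 0 genes passed. The vehicle sets also part the families (1 split, 6145, highest other 1982). Within 1 family, the real split of tunicamycin against Ceapin-A7 gave the most genes (1 split, 1746, highest other 1030). That excludes a chance split of these libraries, in a comparison added after the data were examined. It does not exclude chance between animals, since the libraries may not be separate animals. Ddx3y also lay under 1 FPKM in 2 of 5 Ceapin-A7 and 0 of 5 tunicamycin libraries. For tunicamycin against vehicle set 2, within 1 table family, 2 of the 100 splits, the real one included, gave as many as 1141. That share is under 0.05, but the other split gave 1592, more than the real one. Which libraries that split grouped was not recorded, so its count does not tell a structure among these 10 libraries from the compound.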
